A study of Mus musculus with 2 samples.

How the data were processed

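Open chromatin in mouse frontal cortex was measured by DNase-seq, in which the nuclease DNase I cuts accessible DNA and the cut ends are sequenced. Per the labels, 2 libraries were made from female B6CASTF1/J mice, F1 offspring of a B6 and a CAST parent, at 10 days of age, and the labels name them biological replicates 1 and 2 of 1 group. The labels also carry the mark "3x", whose meaning is not given in the sources used here.

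Per the file headers and text files deposited with them, each library has 2 peak lists, a footprint list and a table of the false discovery rate of the local cut rate, all in the coordinates of assembly mm10 and called per library from filtered alignments. The aligner, the callers, their versions and their thresholds are not given in the sources used here. The peak signal is the authors' value for each peak in the deposited lists. It was taken here as a depth-normalised cut density, though its scaling is not stated. Its values were whole multiples of a step that differed between the libraries (100% of values within 0.05 of a step). The signal was used to rank and describe peaks, and to compare libraries only after centring on their median difference. The authors' deposited false discovery rates (a p-value type of measure, at most 0.04991 and 0.04998 in the tables) were used to describe the peak lists. Every peak of the shorter list reached a rate of 0.001 or lower in that table, and every peak of the longer list was listed in it. The value deposited with each footprint was 0.01 in all rows, so footprints could not be ranked.

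The peak list used was to be the one with the smaller median width. Both lists of each library had a median width of 200 bp, so the smaller mean width decided, which selected the longer list in both libraries. This tie rule was set after the widths were seen. The remaining lists, windows, gene lists, motifs and tests were fixed before the data were examined, except where the closing part says otherwise.

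Peak positions were set against GENCODE mouse release M21 on GRCm38, and sequence came from GRCm38.p6. Peaks were shared if they overlapped by at least 1 bp, and chance sharing was estimated after shifting the other list by 1 Mb. A peak was assigned to a start site if its centre lay within 1 kb of one, otherwise to an exon, an intron or intergenic sequence. A promoter was called open if a peak lay within 500 bp of any annotated start site of the gene. Distal density was the number of peaks whose centre was over 1000 bp from every start site, per 100 kb of gene body with 20 kb on each side.

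The 25 gene lists comprised markers of cortical cell types, other brain regions and other organs, gene programs, housekeeping genes, sex-linked genes and the Hox and olfactory receptor families. The Y-linked list was described without a test, and 24 lists were compared with 10000 random lists of protein-coding genes of the same size. Random lists were matched on quintiles of promoter CpG observed/expected ratio for promoters and of region length for distal density. The CpG ratio was taken at the annotated gene start, and the number of start sites per gene was not matched. The two-sided permutation p was adjusted by Benjamini-Hochberg over the 24 lists within a library. A list was called only if its adjusted p was under 0.05 in both libraries in the same direction. These tests take the gene as their unit, so they compare lists within these libraries and not animals or conditions, and genes next to each other in a cluster are not independent. Only the 5 protein-coding members of the X-inactivation escape list entered the tests.

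Exact matches to 22 consensus sequences were found on both strands within peaks. A match was under a footprint if at least 0.5 of it was covered. Each consensus was set against up to 20 shuffles of its letters, using shuffles with at least 10 matches, and tested if at least 10 such shuffles remained. A motif stood apart if its share was above or below that of every shuffle used, in both libraries.

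Genes were named by a rule fixed in advance: of each list the 2 with the highest and the 1 with the lowest mean promoter signal, of each list called for distal density the 2 with the highest density, the 10 highest promoters, the 10 highest distal densities among loci of at least 50 kb, and the 5 strongest promoters open in 1 library only for each library, with the X-escape and Y-linked lists in full. Genes outside this rule are named only where a count is 5 or fewer or where the text says that they were chosen after their values were seen.

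The code was tested on simulated data. Interval overlap gave 0 differences from a direct search over 800 intervals. Simulated sets held 20000 genes and lists of 18, and planted promoter lists were drawn only from the gene classes most often open. The promoter test called 24 of 40 planted lists with a share of 0.3 of their members closed and 40 of 40 with 0.6 closed. These counts do not cover lists of genes that are less often open. It called 0 and 2 of 200 unchanged lists, which were drawn from all classes. The distal test called 1 of 40 lists planted at 2-fold density, 22 of 40 at 4-fold, and 0 of 200 unchanged lists in either simulation. A planted footprint share of 80% was found as 82.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used. The alternatives were the shorter peak list, the strongest 50% of peaks, equal peak numbers, 50% reciprocal overlap, other windows and flanks, gene starts alone, covered bases, unmatched random lists, an overlap of 1 bp with a footprint, each library alone and, chosen after seeing the data, the peaks shared by both libraries.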

Results

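DNase-seq peaks, footprints and cut-rate tables were examined for 2 libraries of frontal cortex from 10 day old female B6CASTF1/J mice. The libraries are biological replicates of 1 group, so the comparisons are between replicates and between sets of genes within each library, and no conditions are compared. Replicate 1 held 104654 peaks with summed widths of 22.5 Mb and replicate 2 held 81654 peaks with 17.4 Mb, with a median peak width of 200 bp in both. Some peaks overlap others of the same list, and each was counted singly here and in the densities below. Read totals were not analysed here. Peak signals were whole multiples of 0.00521 in replicate 1 and of 0.0113 in replicate 2. If 1 step is 1 cut after scaling to 1 M cuts, the steps correspond to 192 and 88.7 M cuts, but the scaling is not stated, so the depth is unknown.

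The strongest peak in both libraries lay on chromosome 17 at 39846781 to 39846920, 107 bp from the start of the noncoding gene Gm42418, with a signal of 43.1 in replicate 1 and 54.0 in replicate 2. Not all leading peaks lay at promoters: one on chromosome 15 from 99735661, with 30.4 and 29.4, was over 10 kb from the nearest start site. Whether reads from repeated sequence raised any of the leading signals was not examined. Other leading peaks lay at the shared start region of Hjurp, which encodes a centromere histone chaperone, and Trpm8, which encodes a cold-sensing ion channel, and at the Dynlt1b start site. The Hjurp and Trpm8 promoters had signals of 28.5 and 32.2 in replicates 1 and 2. Dynlt1b had 21.4 and 26.9. Tle4, a corepressor gene used as a marker of deep-layer cortical neurons, was also among the 10 highest promoters by the mean of the libraries, with 13.5 and 18.8. How far the replicates hold the same open sites was then asked. Of the peaks of replicate 1, 64.8% overlapped a peak of replicate 2, and 82.9% of the replicate 2 peaks overlapped one of replicate 1. After a shift of 1 Mb these shares were 1.73% and 2.11%. Sharing depended on peak signal: it was 23.9% in the lowest and 98.8% in the highest signal quintile of replicate 1, and 53.2% and 99.6% in replicate 2. Across the 65307 peaks shared 1 to 1, the Pearson correlation of log2 signal was 0.967 and Spearman's rho was 0.954. This is a correlation across peaks, which are not independent replicates. The log2 difference, replicate 1 minus replicate 2, had a median of -0.25 and an SD of 0.32. Requiring 50% reciprocal overlap lowered the shares to 52.8% and 67.6%. With equal peak numbers in both libraries, the shares at 1 bp overlap were 75.9% and 76.1%, so nearly the same in both directions.

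**Figure D1:**
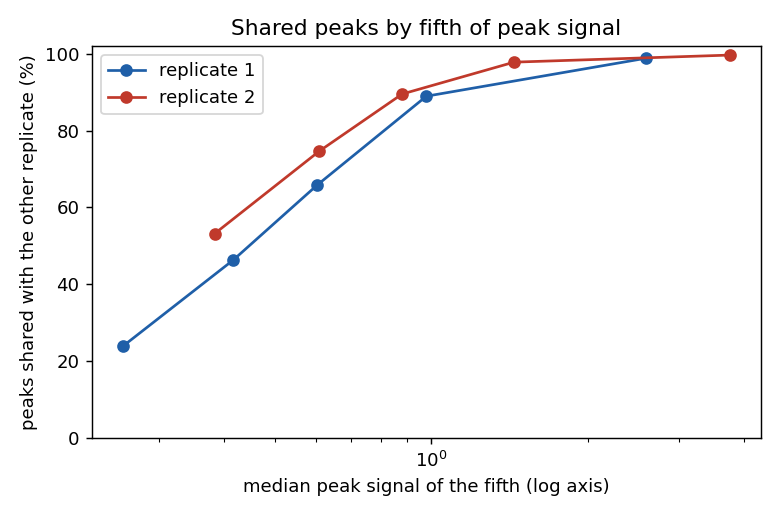
Share of peaks overlapping a peak of the other replicate (percent, vertical axis) against the median peak signal of each quintile (horizontal log axis), 1 line per replicate. The shares run from 23.9% to 98.8% in replicate 1 and from 53.2% to 99.6% in replicate 2.

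Open sites were concentrated at gene starts. Regions within 1 kb of an annotated start site held 33.5% of the peaks in replicate 1 and 36.5% in replicate 2, against 6.05% of the genome. Introns held 31.1% and 29.6% of the peaks against 38.3% of the genome, and intergenic sequence held 30.2% and 29.5% against 52.4%. Exons away from start sites held 5.25% and 4.43% of peaks and 3.18% of the genome. Start-site peaks were stronger, with a median signal of 1.01 and 1.41, than intronic peaks, with 0.531 and 0.756. Narrowing the window to 100 bp lowered the start-site share to 14.1% and 16.4%, against 0.765% of the genome.

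With a peak at any annotated start site counted as open, promoters of pan-neuronal and synaptic genes were open more often than those of random genes. Promoters of liver, skeletal muscle, monoaminergic, Hox and olfactory receptor genes were open less often. Random lists were not matched on the number of start sites per gene, and genes with more of them have more chances to be open. All 20 pan-neuronal and synaptic genes were open in both replicates, against 81.4% and 78.6% expected from random lists with matched promoter CpG content (permutation adjusted p = 0.0137 and 0.00480, two-sided, Benjamini-Hochberg over the 24 lists of a library). Dlg4, which encodes the postsynaptic scaffold PSD-95, had a promoter signal of 4.27 and 4.75 in replicates 1 and 2, Syn2, which encodes a synaptic vesicle protein, had 4.15 and 4.66, and the neurofilament gene Nefm, the lowest of the list by the mean of the libraries, had 1.01 and 1.39. None of the 16 liver genes was open in either replicate (0 of 16, expected 33.1% and 28.7%, permutation adjusted p = 0.0125 and 0.0276), among them Alb and Apoa1, which encode plasma proteins made by hepatocytes. Of the 16 skeletal muscle genes, 3 and 2 were open (permutation adjusted p = 0.0125 and 0.00480), with Mylpf, a myosin light chain gene, at 4.09 and 4.07 and Myh1 at 0 in both. Of the 12 monoaminergic genes, 5 and 4 were open (permutation adjusted p = 0.0128 and 0.00640). Th, which encodes tyrosine hydroxylase, was listed at 0 in both libraries, whereas Dbh, which encodes dopamine beta-hydroxylase, had 1.34 and 1.86. The Hox family was open at 7 and 5 of 39 promoters against 86.8% and 83.8% expected (permutation adjusted p = 0.00240 and 0.00160). Hoxa7 had the highest signal of the family, 1.85 and 2.33. Of 1091 olfactory receptor genes, which encode odorant receptors of the nose, 13 and 17 were open against 17.1% and 14.7% expected (permutation adjusted p = 0.00240 and 0.00160). For the Hox and olfactory receptor families these adjusted values derive from a permutation p of 0.0002, the smallest 10000 lists can give.

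The remaining lists were not called: 5 passed the promoter test in 1 library alone and the others in neither. All 20 excitatory neuron genes were open in replicate 1 and 18 in replicate 2 (permutation adjusted p = 0.0192 and 0.223), and the deep-layer factor gene Fezf2 had 0.542 in replicate 1 and no promoter peak in replicate 2. Of the 18 astrocyte genes, 17 and 15 were open (permutation adjusted p = 0.0125 and 0.111), led by Glul, which encodes glutamine synthetase, at 5.69 and 6.56. Endothelial genes (8 and 5 of 15, permutation adjusted p = 0.417 and 0.0158), choroid plexus and ependymal genes (5 and 3 of 14, permutation adjusted p = 0.386 and 0.0379) and hindbrain and cerebellar genes (9 and 5 of 15, permutation adjusted p = 0.131 and 0.00160) passed the test only in replicate 2, all toward fewer open promoters. The difference between the replicates itself was not tested for these lists. Inhibitory neuron genes were open at 17 and 16 of 20 promoters, oligodendrocyte precursor genes at 12 and 10 of 15, myelinating oligodendrocyte genes at 7 and 8 of 15, microglial genes at 8 and 5 of 16, mural and fibroblast genes at 9 and 5 of 15, and progenitor and newborn neuron genes at 14 and 13 of 15. None of these 6 lists passed the test in either replicate. Housekeeping genes were all open (20 of 20), as were cell cycle genes (16 of 16) and activity-induced genes (18 of 18), but their random lists were also mostly open. Striatal genes were open at 14 of 15 promoters in both, erythroid genes at 4 and 2 of 12 and lymphocyte genes at 3 and 2 of 15, with no call, and the 5 protein-coding genes of the X-escape list were all open (permutation adjusted p = 1 in both). Over all 21701 genes tested, 66.6% and 63.8% had an open promoter, and 13741 were open in both. The 720 open in replicate 1 only were led by Gm26558 at 5.16, and the 113 open in replicate 2 only by Pou3f1, a POU-domain factor gene, at 4.07. The pan-neuronal, monoaminergic, liver and muscle calls were lost with a 2000 bp window (larger permutation adjusted p of the 2 libraries 0.0780, 1, 0.453 and 1) and with the annotated gene start alone (0.0560, 0.0560, 0.212 and 0.0816), the liver call also with the shorter peak list and the strongest 50% of peaks (0.0557 and 0.0904), the muscle call with the shorter list (0.0507) and the monoaminergic call with unmatched lists (0.199). The Hox and olfactory receptor calls held under every alternative run.

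**Figure D2:**
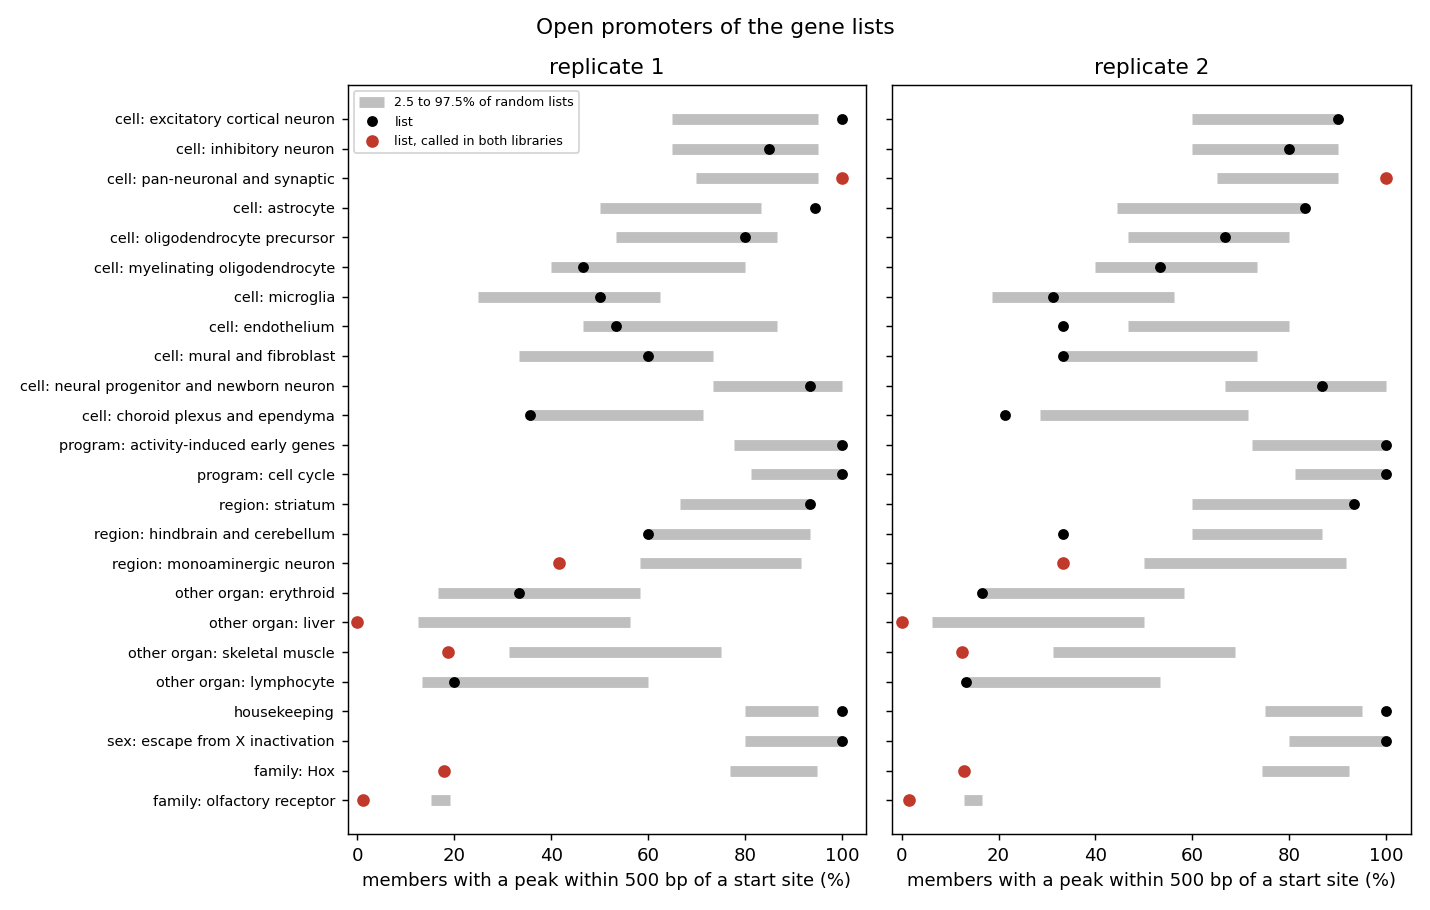
Percent of each gene list with a peak within 500 bp of a start site (horizontal axis), 1 panel per replicate. Grey bars span the central 95% of 10000 random lists and red points mark the 6 lists called in both libraries; the pan-neuronal list lies at 100% and the liver list at 0% in both.

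Distal open sites were denser than around random genes at activity-induced, progenitor and newborn neuron and excitatory neuron genes, and sparser at olfactory receptor genes. The 18 activity-induced early genes, which are transcribed rapidly after neuronal firing, had a median of 11.5 and 7.85 distal peaks per 100 kb in replicates 1 and 2 against 2.37 and 1.66 expected (permutation adjusted p = 0.00240 in both, two-sided). Within this list the highest mean densities of the 2 libraries were at Nr4a1, which encodes an orphan nuclear receptor (chromosome 15, 101254269 to 101274795), with 51.2 and 11.6, and at Egr1, with 33.2 and 15.5. The 15 progenitor and newborn neuron genes had a median of 7.13 and 7.06 against 2.23 and 1.49 (permutation adjusted p = 0.0132 and 0.00240), with the highest means of the 2 libraries at Sox4 (chromosome 13, 28948919 to 28953713), 24.6 in both, and Insm1, which encodes a zinc-finger factor of newborn neurons, 20.9 in both. The 20 excitatory neuron genes had 5.87 and 4.01 against 2.69 and 2.03 (permutation adjusted p = 0.00800 and 0.029997). Within that list, Fezf2 had 36.9 in replicate 1 and 0 in replicate 2, and Tbr1, a deep-layer T-box factor gene, had 17.6 and 5.86. Fezf2, Tbr1 and Nr4a1 lie in 50 kb windows with at least 10 peaks of replicate 1 that replicate 2 lacks, as does Tada1. Olfactory receptor loci had a median of 0 in both replicates against 2.16 and 1.97 (permutation adjusted p = 0.00240 and 0.0272), and 83.0% and 88.1% of them had no distal peak, against 26.1% and 32.1% of all tested genes, whose regions were not matched in length. The other 20 lists were not called, including astrocyte genes, whose median of 6.05 and 3.57 passed the test in replicate 1 alone (permutation adjusted p = 0.0163 and 0.178), and inhibitory neuron genes, with 4.82 and 2.00. Over all genes, the loci of at least 50 kb with the highest mean densities of the 2 libraries included Nfic, a nuclear factor I gene (chromosome 10, 81396186 to 81455635), with 52.3 and 57.3, and its neighbour Celf5, with 41.0 and 42.5, while Tada1 had 62.4 and 1.83 and Bcl9l had 59.4 and 2.90. The remaining lists had medians between 2.27 and 4.68 in replicate 1 and between 0.524 and 3.85 in replicate 2, those of pan-neuronal, oligodendrocyte, microglial, vascular, choroid plexus, cell cycle, other region, other organ, housekeeping, X-escape and Hox genes, and none passed in either library.

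The activity-induced call held under every alternative run, among them the peaks shared by both libraries, an alternative chosen after seeing the data (7.26 and 7.43, permutation adjusted p = 0.00240 in both). The olfactory receptor list could not be judged with shared peaks, the shorter peak list, the strongest 50% of peaks or no flank, where many random lists also have a median of 0, and the excitatory call was lost with shared peaks (2.28 in both, permutation adjusted p = 0.453 and 0.512), with the shorter peak list, the strongest 50% of peaks, 100 kb flanks, covered bases and unmatched lists, and the progenitor call was lost with the shorter peak list, no flank and 100 kb flanks.

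**Figure D3:**
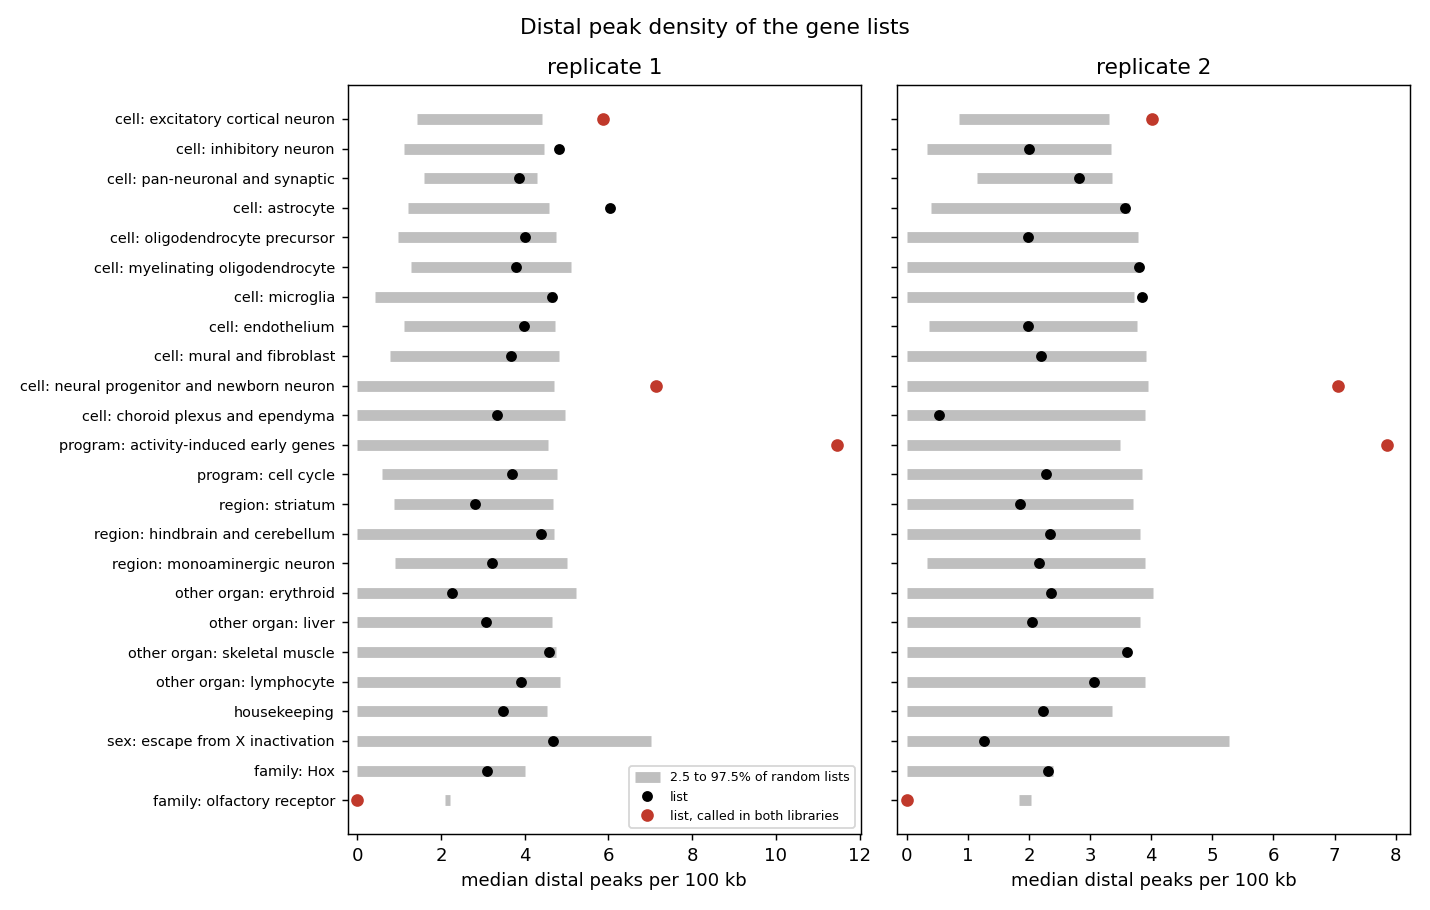
Median distal peaks per 100 kb of gene body and flanks for each gene list (horizontal axis), 1 panel per replicate with its own scale. Grey bars span the central 95% of 10000 random lists and red points mark the 4 lists called in both libraries; the activity-induced list lies at 11.5 and 7.85.

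The X chromosome carried fewer peaks per Mb than the autosomes. There were 17.3 and 12.9 peaks per Mb on X against 42.5 and 33.2 on autosomes, a ratio of 0.407 and 0.389. These densities were not adjusted for the number of genes. Of protein-coding genes, 47.6% and 44.0% on X and 62.0% and 59.1% on autosomes had a peak at the gene start. All 8 genes of the X-escape list were open at a start site in both replicates, which does not set them apart, since 97.2% and 95.9% were expected for its 5 protein-coding members. Kdm6a, a histone demethylase gene, had a promoter signal of 14.4 and 17.5, Kdm5c had 7.73 and 8.04, Ftx had 6.62 and 7.07, Ddx3x had 5.43 and 6.01, Pbdc1 had 5.17 and 6.34, Eif2s3x had 3.59 and 5.10, Jpx had 2.13 and 2.45, and Xist, the RNA that silences one X, had 0.953 and 1.39. None of the 8 Y-linked genes examined, Ddx3y, Uty, Kdm5d, Eif2s3y, Zfy1, Zfy2, Sry and Usp9y, had a promoter peak in either replicate, and 0 of 183 protein-coding genes on Y had a peak at the gene start. The Y chromosome nevertheless carried 37 and 25 peaks. The peak counts on X and Y were not tested.

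Footprints, short stretches protected from DNase I, covered matches to several factor motifs more often than shuffled sequences. Replicate 1 held 293484 footprints and replicate 2 held 187137, with a median width of 10 bp, and 82.8% and 85.3% lay inside peaks. Of all footprints, 37.3% and 60.3% overlapped one of the other replicate, against 0.266% and 0.388% after the 1 Mb shift. Matches to CTCF, the insulator-binding factor, lay under a footprint in 93.8% of 5435 sites in replicate 1 and 82.9% of 4854 in replicate 2, against shuffle medians of 22.1% and 17.2%. NRF1 matches reached 91.9% and 90.02%, and CRE matches, bound by the CREB family, 78.6% and 71.2% against 11.9% and 9.89%. The full NFI site reached 79.8% of 119 and 40.7% of 81 matches, RFX 68.7% and 47.2%, EGR 64.9% and 60.2%, and ETS 37.8% and 29.0%. These 7 motifs lay above every shuffle used in both replicates, ETS in replicate 1 by little (37.8% against 36.4% in its highest shuffle). MEF2, at 19.1% and 12.4%, and the proneural E-box, at 29.5% and 22.1%, did so in replicate 1 alone, and the myeloid PU.1 motif, at 12.8% and 11.4%, in replicate 2 alone. AP-1, at 10.6% and 7.63% of 4483 and 3527 matches, lay within its shuffles, as did the POU, SOX, homeobox, ROR, GATA, HNF4 and TEAD motifs. REST, YY1 and SP/KLF had too few usable shuffles, with 55.8% and 39.4%, 48.7% and 42.8%, and 65.1% and 55.8% of their matches under footprints, and HNF1 had 0 matches. The 8 usable SP/KLF shuffles reached up to 65.1% and 55.4%, nearly the shares of the motif itself. The 6 and 5 usable YY1 shuffles reached up to 40% and 27.3%, and REST had 0 usable shuffles. ETS was no longer above every shuffle in both replicates with the shorter peak list, the strongest 50% of peaks, equal peak numbers and shared peaks, and RFX could not be tested in the first 2 of these. Shuffles kept the letters of a consensus but not pairs such as CpG, and their matches were not matched on peak signal. Peaks with a footprint had a higher median signal (0.703 and 1.17) than peaks without one (0.318 and 0.474).

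**Figure D4:**
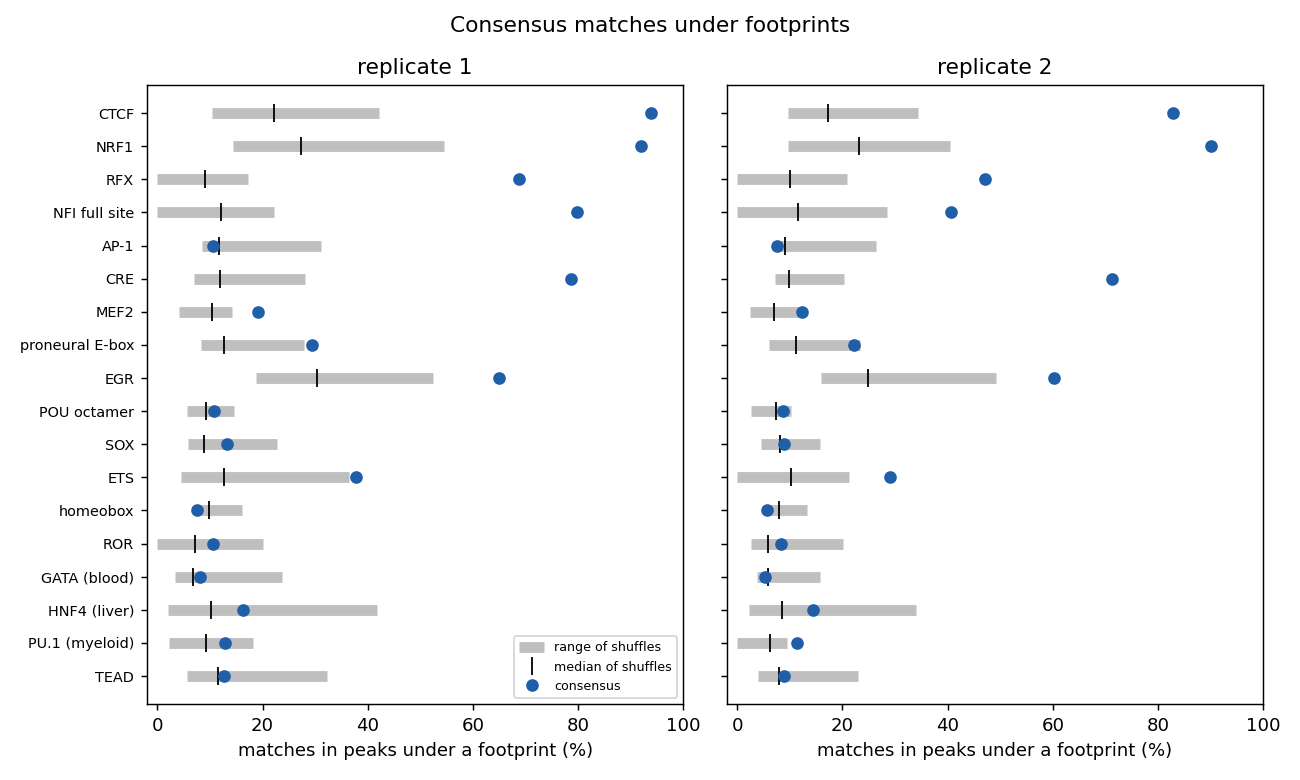
Percent of consensus matches in peaks that lie under a footprint (horizontal axis), 1 panel per replicate, for the 18 motifs with enough shuffles. Blue points are the consensus, grey bars the range and black ticks the median of the shuffles; CTCF lies at 93.8% and 82.9%.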

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

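The count of Y-linked promoters, both tests of a single signal cutoff and the test of local cutoffs were chosen after their values had been seen, and the tests of shared sequence and of shared peaks inside dense runs were not.

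Although the labels give female animals, the cut-rate tables listed 11012 bases of the Y chromosome in replicate 1 and 10052 in replicate 2, in data that no comparison used. The peak lists held 37 and 25 Y peaks, of which 22 and 19 lay between 90717601 and 90744820. Male cells are argued against by the 8 Y-linked genes, of which 0 had a promoter peak in either library, though this speaks only to a share of cells large enough to give peaks. Sequence shared with other chromosomes may account for part: 31.9% of the 36-base words of the Y peaks occurred on another chromosome, 71.2% before 90 Mb and 19.1% beyond it. That share lies between the bounds set in advance, so shared sequence stays open. Only exact matches within the reference assembly were counted, so sequence shared in a diverged form, as may occur in the CAST genome, would be missed.

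Replicate 1 held 292 windows of 50 kb with at least 10 peaks unshared with replicate 2, against at most 10 in 100 random placements. Replicate 2 held 9 such windows, against at most 1 in its own random placements. The windows of replicate 1 held 13.1% of its unshared peaks, and windows of this kind lay at Fezf2, Tbr1, Nr4a1 and Grin1, of which Grin1 was chosen after its values were seen. A single signal cutoff for the whole genome is argued against for the window peaks that the shorter list kept: it kept 58.9% of the unshared peaks in the windows and 17.3% of those outside, and 82.4% of the outside peaks it left out had a signal above the median of the window peaks it kept. For the longer list, deeper sequencing with a single cutoff stays open, because the first test written for it, met by a median signal in the windows of 0.245 against a 5th percentile outside of 0.161 and a median outside of 0.385, set too low a bound to decide. A truly more open stretch in the replicate 1 tissue is argued against for the peaks both libraries share. The 1244 such peaks inside the windows had a median log2 difference, replicate 1 minus replicate 2 after centring, of 0.029. That median met the bound set in advance as speaking against this explanation, and the SD of 0.29 describes single peaks. Unshared peaks have no replicate 2 signal and are not covered. A signal cutoff that differs between stretches stays open. The median lowest signal per window, 0.151, lay between the 1st and 5th percentiles outside, 0.0990 and 0.161. Every peak of replicate 1 reached a deposited false discovery rate of 0.000992 or lower in the shorter list and 0.0499 or lower in the longer. How that rate relates to signal was not examined.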

How the results depend on the processing

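The alternative of using only shared peaks was chosen after seeing the data; the rest were set in advance. No list or motif changed direction between calls in any alternative. Of 240 list values each over 10 settings, 207 for promoters and 223 for distal density stayed on the same side of the threshold. For promoters and distal density, 12 and 13 lost a call and 21 and 4 gained one. Of 124 motif values over 7 settings, 110 stayed, 4 lost and 10 gained one. These settings include each library alone, which could gain but not lose a call, since a call required both libraries. The mean of 93154 peaks per library became 53964.5 with the shorter list and 46577 with the strongest 50%, by construction. Mean sharing of 73.8% became 60.2% with 50% reciprocal overlap. The Pearson correlation was 0.965 in the strongest 50%. The mean start-site share of 35.0% became 45.6% with the shorter list, 48.7% with the strongest 50%, 37.6% with equal peak numbers, 15.2% with a 100 bp window and 41.9% with 2000 bp. Of 6 lists called for promoters, the count became 3 with a 2000 bp window (4 lost, astrocyte gained), 2 with gene starts alone (4 lost), 10 with unmatched lists (monoaminergic lost, 5 gained), 10 with shared peaks and 9 with the strongest 50% (both gained endothelial, choroid plexus, hindbrain and housekeeping genes, the second lost liver), 7 with equal peak numbers (hindbrain gained) and 5 with the shorter list (liver and muscle lost, hindbrain gained). Of 4 lists called for distal density, 2 were called with the shorter list (1 of them gained, myelinating oligodendrocyte), with the strongest 50%, with 100 kb flanks and with shared peaks; no flank gave 4, of which astrocyte and hindbrain were gained, and covered bases and unmatched lists gave 3 each. The causes were not tested, except that the olfactory receptor distal test is void with the shorter list, the strongest 50%, no flank and shared peaks, where many random lists also have a median of 0. ETS was no longer above every shuffle in both libraries with the shorter list (34.8% mean share), the strongest 50% (34.4%), equal peak numbers (33.7%) and shared peaks (34.4%). MEF2 was above every shuffle in both with a 1 bp overlap (28.2%), the shorter list (23.1%) and shared peaks (16.8%), the proneural E-box with a 1 bp overlap (30.4%), the shorter list (36.01%) and the strongest 50% (34.7%), and PU.1 with a 1 bp overlap (19.3%). With replicate 1 alone, MEF2 was at 19.1%, the E-box at 29.5% and PU.1 at 12.8%, and 8 promoter and 5 distal lists were called. With replicate 2 alone, these were 12.4%, 22.1% and 11.4%, and 9 and 4 lists. Ranking footprints could not be run, since their deposited value is constant, and sharing and correlation have no value with 1 library. No paired analysis was possible because the design has 1 group. The depth is unknown, so how far it limits the weaker peaks of replicate 2 cannot be said, and the distal test called 1 of 40 simulated lists at 2-fold density, so lists without a call are not shown to be unchanged.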

Other observations

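The test of peak numbers below was chosen after its values were seen, and the test of signal at shared peaks was not, although the 4 lists were chosen from their promoter counts and the bootstrap interval was added after the median was seen; the Hox family was singled out after the values of all 23 lists were seen.

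At the peaks both libraries share, the Hox family had the lowest value of the lists compared. Around 32 of its 39 genes with such peaks, the median log2 signal, replicate 1 minus replicate 2 after centring, was -0.18, against -0.05 to 0.11 in random lists matched on length (permutation adjusted p = 0.0230 over 23 lists, two-sided, 2000 random lists). Hox genes sit in clusters and share peaks, unlike the genes of the random lists, so this p is too small by an unknown amount and shows no difference between the replicates. No other list passed, with the monoaminergic list at -0.13 and the mural and fibroblast list at 0.14 (permutation adjusted p = 0.161 in both).

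Inhibitory neuron, endothelial, mural and fibroblast, and hindbrain genes together had 43 of 65 promoters open in replicate 1 and 31 in replicate 2. The inhibitory list differed by 1 gene (17 and 16 of 20), and microglial (8 and 5 of 16) and choroid plexus genes (5 and 3 of 14), which were not in this set, were also lower in replicate 2, as was the share over all genes (66.6% and 63.8%). One hypothesis is a different cell makeup of the 2 tissue samples, which may raise the signal of their shared peaks in replicate 1. The median centred log2 difference over the 4 lists was 0.055, with a 95% bootstrap interval over 59 genes of -0.06 to 0.15. The median itself met the bound set in advance as speaking against this explanation, but the interval, added afterwards, reached past that bound, so the test is left undecided. A lower depth of replicate 2 is a second candidate explanation. With equal peak numbers the counts were 39 and 31, a difference of 8 in place of 12, so neither explanation could be decided.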
